A study of Mus musculus with 8 samples.

How the data were processed

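RNA was measured in CD4+ T cells that had been sorted by flow cytometry from spleens and lymph nodes, combined, of mice on the C57BL/6J background. The mice had received bone marrow progenitors that carried a T cell receptor (TCR) beta transgene, lacked the endogenous TCR alpha gene, and had been transduced with a retrovirus encoding 1 of 2 TCR alpha chains, called ANT and SAS. Cells of such retrogenic mice share a receptor, so each group is referred to here as a clone. Per the labels, sorted cells were lysed in TRI Reagent, RNA was extracted with chloroform and isopropanol, and strand-specific libraries were made with Illumina's TruSeq mRNA kit. There were 4 ANT libraries (replicates 1, 3, 4 and 5) and 4 SAS libraries (replicates 1, 2, 3 and 6), and the group and replicate number of each were taken from its title and treatment label.

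The authors deposited 1 table of raw counts per gene, in whole numbers, for 39056 versioned Ensembl genes and 8 libraries. Reads were aligned with STAR to mm10 and counted with featureCounts, per the submitters' processing notes. Their versions, the annotation release, the strand setting and the treatment of reads that map to several places were not given in the sources used here. Gene IDs were matched to GENCODE M21, an annotation of the same genome build (GRCm38, mm10). Without the version suffix 38872 IDs matched and 184 did not, and 34299 matched with the suffix. Symbols, coordinates and lengths come from that annotation. Because the handling of multi-mapped and overlapping reads is unknown, counts of genes with near-identical copies (TCR variable segments, Ly6c1 and Ly6c2, the Bcl2a1 genes, ribosomal protein genes with processed pseudogenes) and of overlapping or antisense genes are uncertain.

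Genes were tested with edgeR 4.0.16 in R 4.3.3 on all 8 libraries. Genes passing the default low-count filter for the 2 groups were kept (12619 genes), libraries were scaled with TMM factors, and the robust quasi-likelihood test compared SAS with ANT without covariates. P-values were adjusted by the Benjamini-Hochberg method, and genes were called at an adjusted p under 0.05. Log2 fold changes are SAS minus ANT. Their standard error (SE) is the absolute log2 fold change divided by the square root of the F statistic. Levels are in CPM, the counts per 1e6 of the TMM-scaled library size, as the mean ± SD of 4 libraries. Where a group held 1 to 3 counts of a gene in all, the ratio is given with its 95% conditional binomial interval, which covers counting error only.

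Gene groups were not taken from these samples: 30 lists with 724 members in all were written from general knowledge before the data were examined, for T cell programs, sample quality and other cell types, and 720 members matched a symbol. Each was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 30 lists, and again with an estimated correlation. Camera asks whether a list's members differ from the other genes. Many genes stand in several lists: 14 of the 27 measured Tfh members, 12 of 23 anergy members, 13 of 29 TCR signal members and 9 of 17 Treg members were also in another list, so these tests are not independent.

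The genes named in the text follow a rule also set at that stage. They are the 12 genes with the largest change in each direction, among called genes with non-overlapping groups and a mean of at least 10 CPM in the higher group, leaving out receptor segments, predicted genes and pseudogenes. Added to these are 29 fixed genes, the 4 members of each program list with the smallest p in its main direction, and the 3 most abundant members of each quality or other-cell list, which gave 135 genes, 134 of them tested. Genes outside the rule, such as the exceptions within a list, were chosen after their values were seen. A few genes that follow from the rule are not reported here. Library measures such as the share of ribosomal protein counts were compared with an exact two-sided permutation test, which cannot give a p under 0.0286 with 4 libraries against 4.

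Library totals were 27600959 to 31810799 counts. At that depth, the tests were checked on simulated counts for the SAS against ANT comparison, drawn for the 12619 genes with 200 of them changed. edgeR recovered 20% of the genes changed 1.5-fold, 56% at 2-fold, 94% at 4-fold and 96% at 8-fold, and 5.67% of its calls were false. Limma-voom had 5.84% false calls and DESeq2 18.6%. These rates hold for 200 changed genes and need not carry over to the data, where far more genes were called. Of 20 unchanged simulated lists, camera called 0. Simulated genes were drawn independently, so this does not test camera on lists whose members are correlated. The estimated correlation was 0.156 for the TCR signal list and 0.855 for ribosomal protein genes.

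The alternatives tried were other scalings (RLE, upper-quartile, library size only), other low-count filters, DESeq2 1.42.0, limma-voom with quality weights, stricter thresholds, removal of receptor segments, a replicate block, an estimated inter-gene correlation, and leaving out each library in turn. The clones share only replicate numbers 1 and 3, so the fit with a replicate block takes the clone difference from those libraries alone. After the data were seen, fits without ANT replicates 4 and 5, without ANT replicates 1 and 3, and with a trend in GC content and length removed were added. All 8 libraries were used and none was merged. The counts of each pair within a clone differed by more than sampling noise, which does not show that the libraries are independent samples. Chi-square per degree of freedom, near 1 for sampling noise alone, was 10.7 between ANT replicates 1 and 3 and 22.1 between ANT replicates 4 and 5. Across these pairs it was 103 to 141, and in SAS it was 25.7 to 100. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.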

Results

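Gene counts were collected from CD4+ T cells of 2 retrogenic clones, ANT and SAS, which share a TCR beta transgene and differ in the TCR alpha chain supplied by retrovirus. The series title concerns self-reactive CD4+ clones that take on a T follicular helper (Tfh)-like state at steady state, and the comparison of SAS with ANT addresses how the expression programs of these clones differ. Each clone had 4 libraries, with 27600959 to 31810799 counts each, and the test of these totals gave an exact permutation p of 0.886 (two-sided). Genes with a count (16950 ± 314 in ANT, 18030 ± 216 in SAS), genes with at least 10 counts (12170 ± 84.0 and 13090 ± 673) and the share of counts in pseudogenes (0.503% ± 0.0289 and 0.352% ± 0.00615) separated the clones without overlap. Each had the smallest possible exact permutation p, 0.0286, or 0.105 adjusted over 11 library measures. The labels number the samples separately but do not state that each came from its own mouse or pool of mice, so p-values measure the spread between these samples, part of which can be technical. In a principal component analysis, the first component held 73.7% of the variance and separated the clones, and the second, with 10.6%, split both clones. ANT replicates 1 and 3 (24.97 and 26.64) and SAS replicate 1 (23.55) lay at one end, and ANT replicates 4 and 5 (−25.1 and −31.33) and SAS replicate 2 (−24.98) at the other.

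The receptor segments, which the design expects to differ, were examined first. Trav9-4, a TCR alpha variable segment (chromosome 14, 53676141 to 53676630, plus strand, mm10), held 48.0% ± 10.5 of all TRAV counts in SAS and 0.548% ± 0.372 in ANT (SD, n = 4). It stood at 29.3 CPM in SAS and 0.288 CPM in ANT, with a log2 fold change of 6.58 and an adjusted p of 1.44e-06. Every SAS library lay between 35.5% and 60.3%, and every ANT library between 0.273% and 1.10%. In ANT, Trav14-1 held 15.3% ± 1.70 of TRAV counts against 2.86% ± 0.881 in SAS, and Trav14d-3-dv8 held 15.4% ± 2.48 against 7.28% ± 1.68. No single annotated segment thus led in ANT as Trav9-4 did in SAS. The large Trav9-4 share lowers the SAS shares of all other segments. Log2 fold changes were −2.12 for Trav14-1 (adjusted p 0.000143) and −0.80 for Trav14d-3-dv8 (adjusted p 0.0273). These variable segments belong to families with near-identical copies, whose reads can be lost or split in gene counts. The joining segment Traj40, picked out after its values were seen, was higher in ANT. It held 3.73% of TRAJ counts in ANT and 0.872% in SAS (log2 fold change −2.10, adjusted p 0.000297). Trbv26 held 95.5% ± 0.515 of TRBV counts in ANT and 95.4% ± 0.399 in SAS, one beta chain segment in both clones. Cd4 was at 936 ± 59.8 CPM in ANT and 907 ± 66.6 CPM in SAS, and Cd3e, a signalling chain of the receptor, at 515 ± 45.3 and 507 ± 18.6 CPM, with adjusted p of 0.753 and 0.878. Thy1, a surface marker of T cells picked out after its values were seen, was higher in ANT, at 917 ± 91.7 against 248 ± 35.3 CPM (log2 fold change −1.89, SE 0.13, adjusted p 3.21e-06), as was the beta constant gene Trbc1 by less (log2 fold change −0.32, adjusted p 0.045). Trac, the alpha constant gene, was higher in ANT, at 318 ± 21.8 against 202 ± 8.75 CPM (log2 fold change −0.65, SE 0.09, adjusted p 0.000293). Gene counts do not separate transcripts of the construct from those of the locus.

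SAS cells carried more transcripts of most measured Tfh genes, of genes induced by TCR signals, of regulatory and anergy-associated genes and of inhibitory and costimulatory receptors. ANT cells carried more transcripts of most measured genes of naive, resting T cells and of interferon-induced genes. Of these lists only Tfh kept its call with an estimated correlation (adjusted p = 0.0213); the others had 0.0597 (TCR signal, anergy and interferon), 0.051 (Treg), 0.16 (naive) and 0.298 (receptors). Lag3, an inhibitory co-receptor that binds MHC class II, was at 196 ± 31.7 CPM in SAS and 0.674 ± 0.0940 CPM in ANT. Bcl6, the repressor that directs Tfh differentiation, was at 118 ± 7.01 against 24.5 ± 1.08 CPM. Ly6c1, a surface protein of resting CD4+ T cells, was at 6.65 ± 0.639 CPM in SAS and 309 ± 74.6 CPM in ANT.

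Of 12619 genes tested, 4725 (37.4%) differed between the clones in edgeR's quasi-likelihood test, 2497 of them higher in SAS and 2228 higher in ANT. At least 2-fold differences were found for 2006 of these genes, 1344 higher in SAS and 662 higher in ANT. The 4 libraries of one clone all lay above the 4 of the other for 4813 genes (38.1%), where chance gives 2.86%. SAS-high genes made up 52.8% of the calls with TMM scaling and 64.8% when libraries were scaled by their totals alone. Under a test against a fold change of 1.5 the count was 1836, and at an adjusted p under 0.01 it was 3044.

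**Figure D1:**
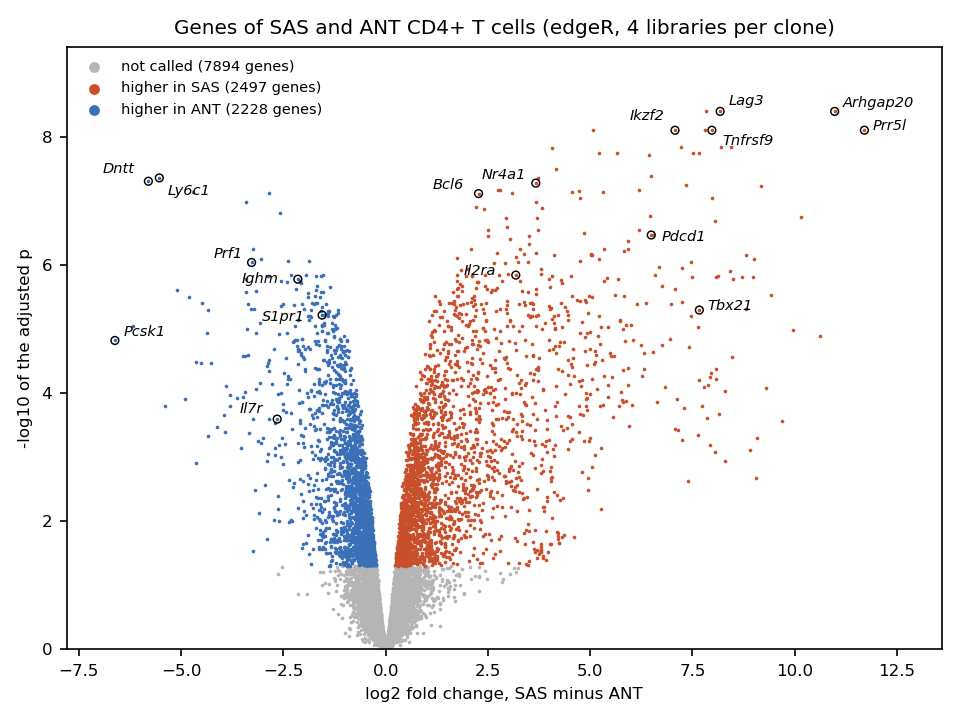
Log2 fold change (SAS minus ANT, horizontal) against −log10 of the edgeR adjusted p (vertical) for the 12619 tested genes, each point a gene, with 2497 genes higher in SAS in orange, 2228 higher in ANT in blue and the rest grey. Circled genes are named in the text, and the SAS-high side reaches larger folds (Prr5l, 11.70) than the ANT-high side (Pcsk1, −6.62).

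The 12 genes with the largest excess in SAS were Prr5l, Arhgap20, Chst3, Samd3, Penk, Kcnc1, Tnfsf4, Kit, Rgs16, Slc9b2, Lag3 and Itgb8. Most were nearly silent in ANT. Prr5l (chromosome 2, 101714285 to 101883027), whose product binds mTOR complex components, had 1 count in the 4 ANT libraries together, in replicate 5, and 5311 in SAS, a ratio of 4939 with a 95% counting interval of 886.1 to 195100. Its level in SAS was 43.7 ± 4.55 CPM. Arhgap20, which encodes a GTPase-activating protein, stood at 97.7 ± 17.6 CPM in SAS and 0.0441 ± 0.0166 CPM in ANT (log2 fold change 10.98, SE 0.27, adjusted p 4.03e-09). Rgs16, a regulator of G protein signalling, stood at 78.7 ± 15.4 against 0.221 ± 0.0986 CPM. Tnfsf4, the gene of OX40 ligand, was at 51.5 ± 21.2 against 0.0960 ± 0.0713 CPM, and Kit, the stem cell factor receptor, at 17.5 ± 5.84 against 0.0431 ± 0.0517 CPM. Penk, the precursor of enkephalins, rested largely on SAS replicate 3, with 102 CPM against 2.01 to 13.2 CPM in the other SAS libraries. Its log2 fold change was 9.05 (SE 1.72, adjusted p 0.00212), 6.78 without SAS replicate 3 and 10.06 without ANT replicate 5, and it was not called by limma-voom (adjusted p 0.0699), without ANT replicates 4 and 5 (0.12) or without ANT replicates 1 and 3 (0.145). The fitted log2 fold changes of genes with few ANT counts moved with single libraries: without ANT replicate 5 that of Prr5l went from 11.70 to 13.32, Chst3 from 10.15 to 10.93 and Itgb8 from 8.13 to 8.81, and without ANT replicate 1 that of Kit went from 8.50 to 9.28 and that of Kcnc1 to 10.41.

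The 12 genes with the largest excess in ANT were Pcsk1, Dntt, Ly6c1, Slc6a19, Klrd1, Slc16a5, Pdlim4, Cd8b1, Epas1, Tent5a, Sorcs2 and Eya2. Dntt (chromosome 19, 41029275 to 41059525), the polymerase that adds untemplated nucleotides to receptor junctions, stood at 74.6 ± 5.58 CPM in ANT and 1.34 ± 0.493 CPM in SAS (log2 fold change −5.80, SE 0.22, adjusted p 4.96e-08). Slc16a5, a monocarboxylate transporter family member, was at 88.5 ± 7.86 against 3.39 ± 0.907 CPM. Klrd1, a lectin-like receptor subunit of natural killer cells, was at 13.2 ± 5.35 against 0.467 ± 0.146 CPM, and Eya2, a transcriptional co-activator, at 25.1 ± 2.07 against 2.36 ± 0.320 CPM. Pcsk1, a prohormone convertase, averaged 20.7 CPM in ANT and 0.208 CPM in SAS. Its log2 fold change was −6.62 (adjusted p 1.52e-05), and −7.28 without SAS replicate 2. Epas1 went from −3.63 to −4.23 without the same library, Pdlim4 from −4.64 to −5.34 without SAS replicate 3, and Slc6a19 from −5.40 to −4.62 without ANT replicate 3.

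Tfh genes were higher in SAS. Of 27 measured members of the list, 20 were higher in SAS, 3 higher in ANT and 4 not called, with the same counts of 20 and 3 adjusted over the list alone (camera adjusted p 7.5e-08; adjusted p = 0.0213 with an estimated correlation). Bcl6 (ENSMUSG00000022508.5, chromosome 16, 23965052 to 23988852) had a log2 fold change of 2.27 (SE 0.09, adjusted p 7.74e-08). Cxcr5, the chemokine receptor that guides cells into follicles, rose from 0.634 ± 0.147 CPM in ANT to 59.4 ± 22.3 CPM in SAS (log2 fold change 6.54, SE 0.33, adjusted p 3.43e-07). Pdcd1, which encodes PD-1, was at 130 ± 37.3 against 1.44 ± 0.564 CPM, and Icos, a costimulatory receptor, had a log2 fold change of 2.23. Pou2af1, a transcriptional co-activator, had a log2 fold change of 4.17, Tox2 of 4.46 and Maf of 1.92. Il21, the cytokine of Tfh cells, was called but scarce, with 103 counts in the 4 SAS libraries and 5 in ANT. Its log2 fold change was 4.13 (adjusted p 0.000653), and 5.70 without ANT replicate 1. The 3 members higher in ANT, picked out after their values were seen, were Il6ra, Cxcr4 and Cd40lg, at −1.04, −0.59 and −0.86. Ascl2, a Tfh transcription factor, had 6 counts in SAS and 5 in ANT and was not tested.

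Genes induced by TCR signals were higher in SAS. Of 29 measured members, 24 were higher in SAS and 0 higher in ANT, or 26 and 0 adjusted over the list alone (camera adjusted p 6.96e-15; adjusted p = 0.0597 with an estimated correlation). Nr4a1 (chromosome 15, 101254269 to 101274795), an immediate response gene of the receptor, stood at 1316 ± 72.3 CPM in SAS and 103 ± 16.2 CPM in ANT (log2 fold change 3.67, SE 0.14, adjusted p 5.31e-08). Nr4a3 stood at 736 ± 127 against 14.5 ± 2.29 CPM, and Tnfrsf9, a costimulatory receptor of activated T cells, at 402 ± 74.5 against 1.60 ± 0.370 CPM. Cd5, whose level follows the strength of self-recognition in the thymus, was at 678 ± 44.8 against 213 ± 28.5 CPM (log2 fold change 1.67, SE 0.12, adjusted p 3.72e-06). Cd69, an early activation marker, was at 460 ± 128 CPM in SAS and 270 ± 112 CPM in ANT, which did not pass the test (log2 fold change 0.77, adjusted p 0.0553). DESeq2 and limma-voom called Cd69, with adjusted p of 0.0252 and 0.0091, and it was also called without ANT replicate 4 (log2 fold change 1.05, adjusted p 0.00846).

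Anergy-associated genes followed the same direction. Of 23 measured members, 17 were higher in SAS, 2 higher in ANT and 4 not called, and 17 and 2 adjusted over the list alone (camera adjusted p 2.21e-07; adjusted p = 0.0597 with an estimated correlation). Izumo1r, which encodes folate receptor 4, stood at 170 ± 43.9 CPM in SAS (log2 fold change 3.60, SE 0.26, adjusted p 4.11e-06). Nt5e, which encodes CD73, stood at 20.9 ± 9.85 against 0.538 ± 0.150 CPM. Egr2 and Egr3, transcription factors of the anergy program, had log2 fold changes of 3.82 and 4.73. Dgka and Sirt1, picked out after their values were seen, were higher in ANT, at −0.90 and −0.41.

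Genes of regulatory T cells were higher in SAS. Of 17 measured members, 15 were higher in SAS and 0 higher in ANT, or 16 and 0 adjusted over the list alone (camera adjusted p 1.15e-10; adjusted p = 0.051 with an estimated correlation). Ikzf2, which encodes the transcription factor Helios, stood at 976 ± 93.0 CPM in SAS and 7.24 ± 1.65 CPM in ANT (log2 fold change 7.07, SE 0.20, adjusted p 7.94e-09). Il2ra, the high-affinity subunit of the interleukin receptor, was at 52.6 ± 11.8 against 5.80 ± 0.988 CPM, Ikzf4 at 25.6 ± 3.47 against 3.38 ± 0.568 CPM, and Swap70 at 115 ± 12.3 against 15.1 ± 2.25 CPM. Ctla4 was at 32.0 ± 18.7 against 5.63 ± 2.46 CPM (log2 fold change 2.51, adjusted p 0.00225). It was not called without ANT replicates 1 and 3 (adjusted p 0.0898). Foxp3, the lineage factor itself, stayed low in both clones, at 1.45 ± 0.716 CPM in SAS and 0.585 ± 0.106 CPM in ANT (log2 fold change 1.31, SE 0.36, adjusted p 0.0165). Foxp3 was not called against a fold change of 1.5 (adjusted p 0.0845), without ANT replicates 4 and 5 (0.0586) or without ANT replicates 1 and 3 (0.0734).

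Genes of naive and quiescent T cells were lower in SAS. Of 26 measured members, 18 were higher in ANT and 0 higher in SAS, or 18 and 1 adjusted over the list alone (camera adjusted p 1.9e-07; adjusted p = 0.16 with an estimated correlation). Il7r, the receptor subunit of a survival cytokine, stood at 86.6 ± 19.8 CPM in SAS and 544 ± 295 CPM in ANT (log2 fold change −2.65, SE 0.36, adjusted p 0.000257). ANT replicates 4 and 5 stood apart for Il7r, at 911 and 653 CPM against 340 and 274 CPM in replicates 1 and 3, and its log2 fold change was −1.84 without the former and −3.17 without the latter. S1pr1, the receptor for lymphoid exit, was at 233 ± 10.4 against 683 ± 104 CPM, Als2cl at 203 ± 39.5 against 854 ± 207 CPM, and Treml2 at 86.1 ± 6.42 against 188 ± 15.8 CPM. The lymph node homing gene Ccr7 had a log2 fold change of −1.20 (adjusted p 0.000164). Klf2, which drives S1pr1, did not pass the test, at 192 ± 136 CPM in SAS and 351 ± 184 CPM in ANT (adjusted p 0.208). It split along the same line in ANT, at 552 and 460 CPM in replicates 4 and 5 against 218 and 174 CPM in replicates 1 and 3. Its log2 fold change of −0.87 ran from −1.42 without SAS replicate 3 to −0.06 without ANT replicates 4 and 5, and no alternative called it. Cd44, a marker of antigen-experienced cells, was slightly higher in ANT (97.2 ± 3.71 against 75.5 ± 10.5 CPM, log2 fold change −0.36, adjusted p 0.0258). That call was lost without ANT replicate 4 (adjusted p 0.0525) and without SAS replicates 2, 3 or 6 (0.0682, 0.0564 and 0.0802).

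**Figure D2:**
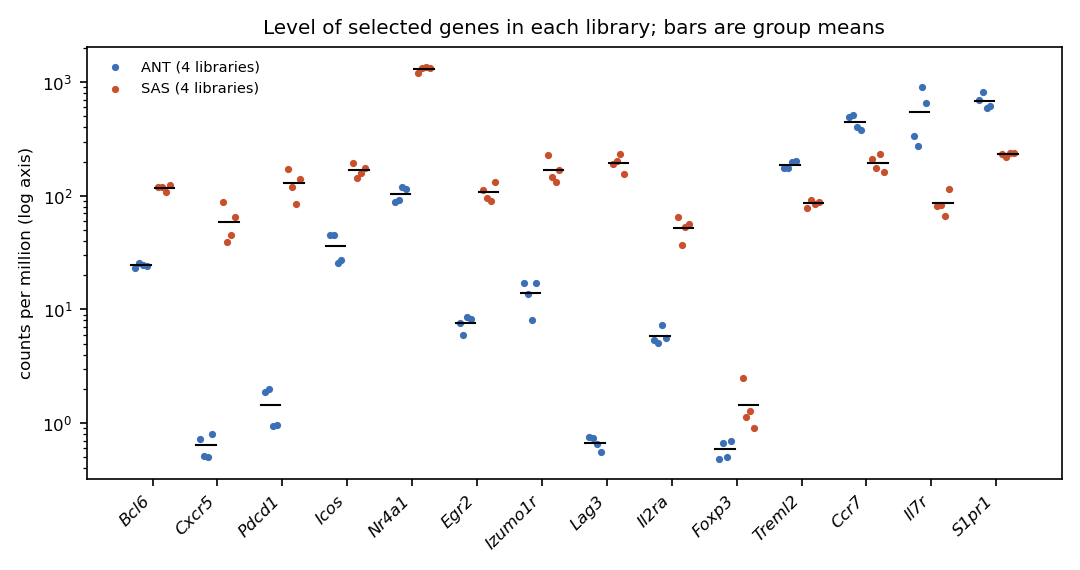
CPM (vertical, log axis) of 14 genes from the text in each of the 8 libraries, with ANT in blue, SAS in orange and a bar at each mean of 4 libraries. The 2 clones do not overlap for any of the genes shown, including Foxp3, which stays near 1 CPM (means 0.585 and 1.45 CPM).

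Th1-associated genes were mostly higher in SAS and split in their direction. Of 20 measured members, 12 were higher in SAS and 5 in ANT, or 13 and 6 adjusted over the list alone (camera adjusted p 0.0103; adjusted p = 0.378 with an estimated correlation). Eomes, a T-box factor of effector cells, stood at 155 ± 18.1 CPM in SAS and 0.679 ± 0.160 CPM in ANT, and Il2rb at 281 ± 23.8 against 3.12 ± 1.05 CPM. Tbx21, the Th1 lineage factor, was at 8.09 ± 3.16 CPM in SAS with 4 counts in all of ANT (log2 fold change 7.67, and 8.99 without ANT replicate 3). Ifng was at 2.31 ± 1.78 CPM in SAS with 7 counts in ANT (log2 fold change 5.12, and 5.83 without ANT replicate 5). Members higher in ANT, picked out after their values were seen, included the cytokine receptor genes Il18r1, Ifngr1, Il12rb2 and Il18rap, with log2 fold changes of −3.06, −1.53, −1.36 and −1.33. The Th2 list was not called (6 members, 2 higher in SAS and 1 in ANT, 3 and 1 adjusted over the list alone; camera adjusted p 0.273). Its chemokine receptors Ccr8 and Ccr4 were higher in SAS, at 5.34 and 2.35, while Gata3, the Th2 factor, did not pass the test (log2 fold change 0.05, adjusted p 0.906). Gata3 was at 42.5 and 39.4 CPM in ANT replicates 1 and 3 and at 80.2 and 75.8 CPM in ANT replicates 4 and 5. It was called without ANT replicates 4 and 5 (log2 fold change 0.56, adjusted p 0.0366). It was also called with a replicate block (0.60, adjusted p 0.000102), a fit that takes the clone difference from replicates 1 and 3 of each clone alone. Its direction turned in other fits, to −0.35 without ANT replicates 1 and 3. In the Th17 list 4 of 7 members were higher in ANT and 0 in SAS, also adjusted over the list alone, and the list was not called (camera adjusted p 0.0641), though it was without SAS replicate 1 (0.0362) and with scaling by library size only. The 4 were Tmem176a, Tmem176b, Aqp3 and Rora. Effector and memory genes went both ways, 13 of 26 higher in SAS and 7 in ANT (14 and 7 adjusted over the list alone; camera adjusted p 0.273). Nkg7, a protein of cytotoxic granules, was at 35.7 ± 9.36 against 0.619 ± 0.405 CPM, and Hopx had a log2 fold change of 3.55.

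Inhibitory and costimulatory receptors were higher in SAS for 16 of 24 measured members and higher in ANT for 4, or 17 and 5 adjusted over the list alone (camera adjusted p 2.67e-05; adjusted p = 0.298 with an estimated correlation). Lag3 (chromosome 6, 124904361 to 124911705) had a log2 fold change of 8.18 (SE 0.19, adjusted p 4.03e-09), Tnfrsf9 of 7.97, Pdcd1 of 6.49 and Tnfsf11, the gene of RANK ligand, of 4.84. Cd226, Vsir, Cd40lg and Ly9, picked out after their values were seen, were higher in ANT, at −1.73, −0.44, −0.86 and −0.36. Cell cycle genes were higher in SAS for 31 of 42 measured members and higher in ANT for 1, or 34 and 1 adjusted over the list alone (camera adjusted p 2.45e-09; adjusted p = 0.219 with an estimated correlation). Mki67, a proliferation marker, was at 28.6 ± 17.3 CPM in SAS (log2 fold change 4.45, SE 0.48, adjusted p 5.24e-05). The replication genes Mcm5 and Cdc6 had log2 fold changes of 1.18 and 2.14. Kif23, picked out after its value was seen, was the member higher in ANT (−1.61).

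Interferon-induced genes were lower in SAS. Of 35 measured members of the type I interferon list, 27 were higher in ANT and 0 higher in SAS, or 29 and 0 adjusted over the list alone (camera adjusted p 2.17e-13; adjusted p = 0.0597 with an estimated correlation). Ifit2, an antiviral protein, stood at 42.1 ± 2.49 CPM in SAS and 136 ± 17.7 CPM in ANT (log2 fold change −1.69, SE 0.11, adjusted p 2.5e-06). Oasl2 was at 7.15 ± 1.09 against 32.8 ± 3.88 CPM, Ddx58, the gene of the RNA sensor RIG-I, at 105 ± 2.17 against 245 ± 23.4 CPM, and Ifi213 at 124 ± 14.5 against 354 ± 44.0 CPM.

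Among metabolic lists, glycolysis had 9 of 19 members higher in SAS and 2 in ANT (9 and 3 adjusted over the list alone) and was not called (camera adjusted p 0.0934). Slc16a3, a lactate exporter, was at 8.86 ± 1.05 CPM in SAS and 0.663 ± 0.301 CPM in ANT. Hk2, hexokinase, was at 8.60 ± 3.74 against 0.151 ± 0.123 CPM (log2 fold change 5.80, and 6.44 without ANT replicate 4), and Pfkfb3 and Pgam1 had log2 fold changes of 1.09 and 1.19. Pdk1 and Slc2a1, picked out after their values were seen, were higher in ANT, at −2.86 and −0.81. Cholesterol synthesis had 8 of 23 members higher in SAS and 2 in ANT (9 and 2 adjusted over the list alone; camera adjusted p 0.236). Oxidative phosphorylation had 6 of 45 members higher in SAS and 1 in ANT, or 1 and 0 adjusted over the list alone (camera adjusted p 0.576), and the list was called without ANT replicates 1 and 3 (0.047). In the list of BCL2 family and death receptor genes, 9 of 20 members were higher in SAS and 4 in ANT (9 and 6 adjusted over the list alone; camera adjusted p 0.236). The survival gene Bcl2l1 was at 38.5 ± 7.22 against 11.2 ± 1.18 CPM.

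Trafficking receptors changed in both directions, 11 of 23 higher in SAS and 9 in ANT, also adjusted over the list alone (camera adjusted p 0.539). Itgal, the alpha chain of the integrin LFA-1, was at 1340 ± 57.6 CPM in SAS and 633 ± 42.1 CPM in ANT. Thymic and progenitor genes had 5 of 15 members higher in SAS and 5 in ANT (6 and 7 adjusted over the list alone; camera adjusted p 0.813). Cd24a, a marker of immature T cells, was at 119 ± 12.1 against 3.56 ± 0.387 CPM, Sox4 at 323 ± 72.9 against 33.3 ± 7.84 CPM, Tox at 251 ± 33.8 against 80.8 ± 2.59 CPM and Id3 at 105 ± 17.4 against 37.0 ± 7.36 CPM. Dntt and Cd8b1 went the other way.

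Cytosolic ribosomal protein genes were lower in SAS for 47 of 76 members and higher for 0, or 55 and 0 adjusted over the list alone (camera adjusted p 8.08e-10; adjusted p = 0.638 with an estimated correlation). Their median log2 fold change was −0.55. The most abundant members, Rpsa, Rplp0 and Rpl4, did not pass the test, with adjusted p of 0.213, 0.228 and 0.0927, though Rpl4 did without ANT replicate 5 (0.0369) and without SAS replicate 1 (0.0468). These genes held 8.56% ± 1.58 of the counts in ANT and 6.26% ± 0.869 in SAS (exact permutation p = 0.0571, two-sided; 0.157 adjusted over 11 library measures), with 9.97% and 9.72% in ANT replicates 1 and 3, 7.91% and 6.64% in ANT replicates 4 and 5, and 5.40% to 7.47% in SAS. Handling-related genes (immediate early and heat shock) had 2 of 22 members higher in SAS and 7 in ANT, also adjusted over the list alone (camera adjusted p 0.321). Fos was at 621 ± 221 CPM in SAS and 738 ± 121 CPM in ANT, Hspa8 at 2341 ± 452 and 1986 ± 261 CPM, and neither passed the test (adjusted p 0.44 and 0.277). Junb, the other of the 3 most abundant members, was higher in ANT, at 890 ± 418 against 320 ± 179 CPM (log2 fold change −1.47, SE 0.43, adjusted p 0.0224), with its highest levels in ANT replicates 4 and 5 (1301 and 1193 CPM). That call was lost without ANT replicates 4 or 5 (adjusted p 0.0556 and 0.0753) and without SAS replicates 1 or 6 (0.052 and 0.0603). Mitochondrially encoded genes had 0 of 13 members called in edgeR, also adjusted over the list alone (camera adjusted p 0.652), and the list was called without ANT replicates 4 and 5 (0.0299). The most abundant, mt-Co1, had an adjusted p of 0.137, and it was called by limma-voom (0.0259) and without ANT replicate 5 (0.0483).

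None of the lists of other cells was called with all libraries. Several of their members were abundant, among them Trdc (457 ± 63.4 CPM in ANT, 397 ± 33.6 in SAS) and Pecam1 (275 ± 45.4 and 252 ± 17.9 CPM). In the B cell list 1 of 12 measured members was higher in SAS and 3 in ANT, also adjusted over the list alone (camera adjusted p 0.576), among them Ighm, the immunoglobulin mu constant gene, at 665 ± 21.4 CPM in ANT and 150 ± 27.1 CPM in SAS (log2 fold change −2.15, SE 0.14, adjusted p 1.68e-06). The other 2 were Bank1, at 2.79 against 0.289 CPM (log2 fold change −3.25, adjusted p 0.000254), and Ighd, at 6.41 against 4.01 CPM (−0.68, adjusted p 0.0324). Cd74 and Igkc stayed under 30 CPM on average in both clones (28.6 ± 15.3 and 18.4 ± 14.1 CPM in SAS, 12.6 ± 7.02 and 16.5 ± 9.98 CPM in ANT). Cd74 was not called with all libraries (log2 fold change 1.19, adjusted p 0.06) but was under 7 of 22 alternatives, among them DESeq2 (0.0213), limma-voom (0.0358), and the fits without ANT replicate 4 (0.026) and without SAS replicate 6 (0.0364). Its log2 fold change ran from 0.65 to 2.42 over the alternatives. The highest came from the fit with a replicate block, which rests on replicates 1 and 3 of each clone alone. Plasma cell markers had 2 of 8 members higher in SAS and 1 in ANT (camera adjusted p 0.857): Irf4 and Xbp1 at 4.01 and 0.46, and Prdm1 at −3.40, all 3 also expressed by T cells. The monocyte, macrophage and neutrophil list had 2 of 8 members higher in each clone (3 and 2 adjusted over the list alone; camera adjusted p 0.576), the dendritic cell list 0 of 5 in SAS and 2 in ANT (camera adjusted p 0.295), and the red cell and platelet list 0 of 5 in SAS and 2 in ANT (camera adjusted p 0.185, and 0.0188 without ANT replicates 1 and 3). In the CD8 T cell list 4 of 8 members were higher in SAS and 2 in ANT, 4 and 3 adjusted over the list alone (camera adjusted p 0.4). Cd8b1 was at 33.6 ± 21.1 CPM in ANT and 2.42 ± 0.725 CPM in SAS, while Cd8a was at 2.56 ± 1.91 and 0.916 ± 0.531 CPM (adjusted p 0.0919). The natural killer and innate lymphoid list had 1 of 4 members higher in SAS and 2 in ANT (2 and 2 adjusted over the list alone; camera adjusted p 0.576), with the cytotoxic gene Prf1 at 3.69 ± 0.886 against 35.8 ± 4.03 CPM. The gamma-delta and NKT list had 3 of 5 members higher in SAS and 0 in ANT (camera adjusted p 0.236), and the stromal and endothelial list 1 of 2 in SAS (camera adjusted p 0.58). For lists given here without a second count, adjustment over the list alone gave the same numbers.

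In all, camera called 10 of the 30 lists, 7 higher in SAS and 3 higher in ANT, and 1 of them, Tfh, with an estimated correlation.

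**Figure D3:**
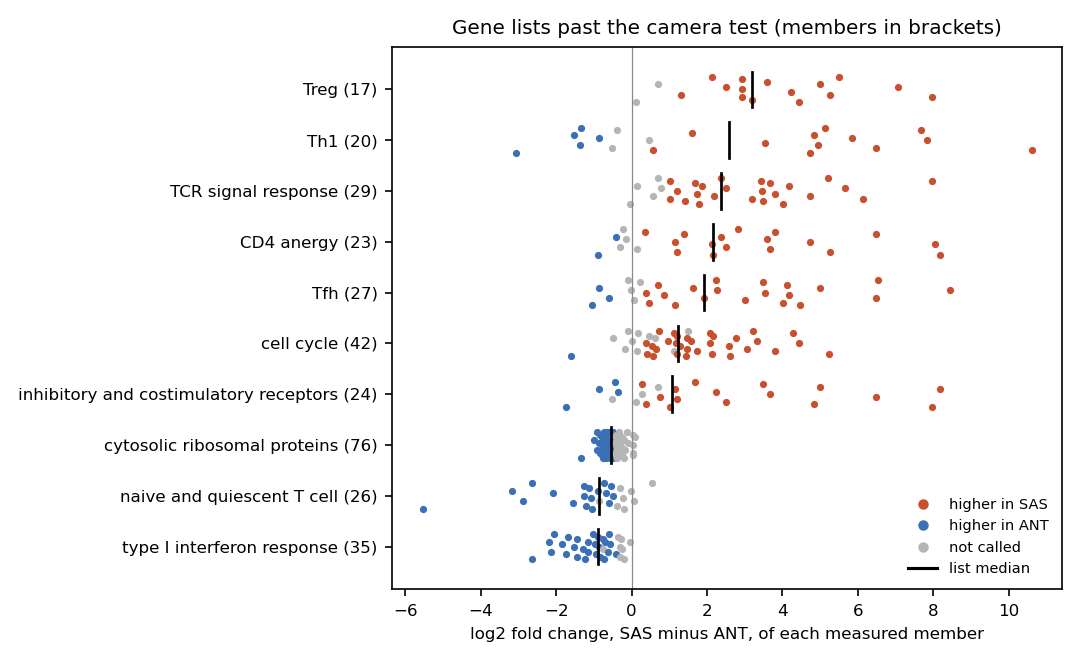
Log2 fold change (SAS minus ANT, horizontal) of each measured member of the 10 called lists, one point per gene, with called members in orange (higher in SAS) or blue (higher in ANT), uncalled members grey and a black bar at the list median. Medians run from −0.88 for the type I interferon response to 3.18 for Treg genes, and the rightmost Th1 point is Xcl1, which had no ANT count and is drawn at its fitted value.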

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

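No test of an explanation was run on the values in this part. In 284 groups of 4 libraries (genes of the naming rule that are reported here, the library measures and the Trav9-4 share, per clone), 16 had 1 library far from the other 3 for the size of the group's range. Chance alone marks about 1 in 20 groups, and 16 of 284 is 5.63%, so no excess was seen. SAS replicates 1 and 2 had 4 such values each.

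In SAS replicate 2, 14090 genes (to 4 digits) had 10 or more counts, while the other SAS libraries had 12650 to 12830. This library also had 2.03% of its counts in long noncoding genes, above 0.954% to 1.25% in the other SAS libraries. Car2 was at 2.45 CPM in SAS replicate 2, above 1.38 to 1.43 CPM in the others, and Hbb-bs at 3.16 CPM, above 0.546 to 0.822 CPM. Ly6c2 was at 0.701 CPM there, below 1.52 to 1.59 CPM.

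Penk was at 102 CPM in SAS replicate 3, where the other SAS libraries had 2.01 to 13.2 CPM. Tnfsf11 was at 39.5 CPM in the same library, just above 34.0 to 34.3 CPM. In SAS replicate 1, Slc9b2 was at 58.1 CPM (others 40.2 to 41.9), Aqp3 at 4.54 CPM (others 1.75 to 2.06), Dhcr7 at 40.9 CPM (others 52.5 to 54.4) and Col1a1 at 0.914 CPM (others 0.578 to 0.631). In SAS replicate 6, Tmem176a was at 0.996 CPM (others 0.518 to 0.561) and Cdc6 at 2.86 CPM (others 3.93 to 4.11).

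In ANT, several of these values amount to a handful of counts. Prr5l was at 0.0345 CPM in ANT replicate 5, its single count, and at 0 in the other 3. In ANT replicate 1, Arhgap20 was at 0.0690 CPM (others 0.0345 to 0.0368) and Slc9b2 also at 0.0690 CPM (others 0.172 to 0.184). In ANT replicate 4, Rora was at 13.3 CPM (others 16.2 to 16.7).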

How the results depend on the processing

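The alternatives chosen after the data were seen were the fits without ANT replicates 4 and 5, without ANT replicates 1 and 3, and with the GC and length trend removed. The count of 4725 differing genes ran from 1836 to 5913 over all alternatives and from 3964 to 4700 when 1 library was left out, and no called gene kept by an alternative changed sign. Stricter thresholds lowered it by construction: at an adjusted p under 0.01, 3044 genes differed and 1306 were higher in ANT, and against a fold change of 1.5, 1836 differed, 1205 higher in SAS and 631 higher in ANT. Without ANT replicates 4 and 5 the count was 5913, without ANT replicates 1 and 3 it was 4779, and with the trend removed 5390, holding 97.2% of the main calls. DESeq2 called 5509 genes, limma-voom 5571, and the unfiltered fit 4600. Library-size scaling moved the median of all genes from −0.0032 to 0.0943 and left 88.1% of the main calls in place.

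With an estimated inter-gene correlation, 1 list was called in place of 10. The adjusted p of the anergy list became 0.0597, of the TCR signal list 0.0597, of the naive list 0.16 and of the Treg list 0.051, while Tfh kept its call at 0.0213. Fry, which tests a list's members without comparing them with other genes, gave these lists adjusted p from 4.47e-08 (Tfh) to 7.22e-05 (naive). It also passed lists that camera did not call, such as trafficking receptors (0.000634). Under the other alternatives in which lists were tested, 10 to 12 were called. Lists were not tested with DESeq2, limma-voom or the stricter thresholds.

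The clones share only replicate numbers 1 and 3. Deviations from the group means correlated at 0.293 between the libraries numbered 1 and −0.121 between those numbered 3, which gave no sign that the numbers pair the samples. A fit with the replicate block called 5798 genes and kept 86.5% of the main calls. Its clone difference rests on replicates 1 and 3 of each clone alone, so it is not a check on all libraries. Across alternatives, the 134 named genes gave 2834 values on the same side of the threshold, 66 that lost a call and 44 that gained one. In simulation at this depth, spread and number of libraries, with 200 of 12619 genes changed, 20% of 1.5-fold and 56% of 2-fold changes were recovered. Far more genes were called in the data (4725). Adjusted p-values depend on the share of changed genes, so these rates need not carry over.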

Other observations

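Of the tests in this part, those of immunoglobulin transcription, of library-to-library variation in ribosomal protein counts, of cell handling, of SAS cells in ANT libraries, of splits with both clones equally in each group and of gene families were chosen only after the result was seen, as were the genes named here outside the rule of the methods.

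Genes were also grouped by the start of their symbols, which gave 180 families of at least 8 tested members. Guanylate-binding protein genes, interferon-induced GTPases, were higher in ANT for 9 of 10 members and higher in SAS for 0 (camera adjusted p 2.21e-05; adjusted p = 0.984 with an estimated correlation). Gbp2 stood at 209 ± 16.8 CPM in ANT and 74.7 ± 21.1 CPM in SAS, and Gbp4 at 692 ± 119 against 286 ± 35.8 CPM. GTPases of the immunity-associated family were higher in ANT for 7 of 9 members and higher in SAS for 1, which did not pass the test (camera adjusted p 0.0505; adjusted p = 0.984 with an estimated correlation). Gimap6 stood at 1269 ± 30.8 CPM in ANT and 715 ± 78.1 CPM in SAS, and Gimap4 at 1019 ± 158 against 561 ± 83.2 CPM. Symbols starting with Bcl, a mixed set of apoptosis regulators and transcription factors, were higher in SAS for 9 of 18 members and higher in ANT for 3 (camera adjusted p 0.0277; adjusted p = 0.984 with an estimated correlation).

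Some genes better known from antigen-presenting cells differed between the sorted T cells. Cd83 was at 7.03 ± 2.01 CPM in SAS and 0.257 ± 0.148 CPM in ANT (log2 fold change 4.75, adjusted p 1.15e-05), and Cd86 at 6.64 ± 1.90 against 2.04 ± 0.533 CPM (log2 fold change 1.70, adjusted p 0.000832), each higher in 4 of 4 SAS libraries than the ANT mean. Trdc, the delta chain constant gene, was abundant in both clones, at 457 ± 63.4 CPM in ANT and 397 ± 33.6 CPM in SAS (adjusted p 0.212). Tcrg-C1, a gamma chain constant gene, had 33 counts in ANT and 35 in SAS in all. Tcrg-C2, another gamma chain constant gene, was called higher in SAS (log2 fold change 3.70, and 5.10 without ANT replicate 1). Over the alternatives its log2 fold change ran from 2.77 to 5.47, with an adjusted p of at most 0.0186.

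Chance in the assignment of libraries to clones was tested over the 35 splits of the 8 libraries into 4 and 4. The real split was the only 1 with as many differing genes (4725), as many higher in SAS (2497) and as many higher in ANT (2228). No other split gave more than 1 gene in any of these counts. The smallest exact permutation p that 35 splits allow is 0.0286, so chance is argued against for these counts but not excluded. Every other split mixes the clones, so few calls there follow from any strong separation of the clones, whatever its source. For the 10 called gene lists the splits do not argue against chance, and they decide little. Of the 35 splits, 12, the real one included, gave 10 or more lists, up to 14. The other 11 all set 3 libraries of one clone with 1 of the other and so keep part of the contrast. The 18 splits with both clones equally in each group, a comparison made after the counts were seen, gave 0 to 7 lists. The clone difference cancels in these splits, and none gave more than 1 differing gene. Camera with the preset correlation thus called lists here without a clone difference. Its small adjusted p-values for the real split are therefore not calibrated for these libraries.

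Ighm was higher in ANT. B cells in the ANT sort are argued against, since Cd79a reached at most 0.146% of the Ighm level in any ANT library and the other 11 tested B cell genes had a median log2 fold change of 0.15, although 2 of them were higher in ANT too, Bank1 (−3.25, at 2.79 CPM in ANT) and Ighd (−0.68, at 6.41 CPM). Plasma cells are argued against by their other abundant transcripts in ANT, where Igkc was at 16.5 CPM and Jchain at 5.23 CPM but Ighm at 665 CPM. Ighg1, left out by the low-count filter, went the other way, with 120 counts in ANT and 4 in SAS. The joining segments Ighj1 to Ighj4 were all higher in ANT, with a median log2 fold change of −4.40, at 1.49 to 2.36 CPM in ANT. A candidate explanation is that the heavy chain locus is transcribed without rearrangement in these T cells, more so in ANT, and a difference between the clones' cells stays open as untested.

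Cytosolic ribosomal protein genes were lower in SAS. A trend with gene length and expression level is argued against as the whole cause. The list's median of −0.55 lay at percentile 0 of 10000 lists matched on both, whose central 95% ran from −0.29 to −0.07. Those lists had a median of −0.16, so part of the difference can follow such a trend. They were drawn gene by gene, while ribosomal protein genes move together (estimated correlation 0.855), so their range is too narrow and the percentile overstates the evidence. The list's median under RLE, upper-quartile and library-size scaling was at most −0.45. These scalings shift all genes alike, and library-size scaling moved the median of all genes only from −0.0032 to 0.0943. That check could therefore hardly have come out otherwise. The list's median was −0.31 without ANT replicates 1 and 3 and −0.77 without ANT replicates 4 and 5. Variation between libraries within a clone stays open: the shares of counts overlapped between the clones, with an exact permutation p of 0.0571, and the set may simply move together from library to library. Reads shared with processed pseudogenes, whose share of counts was also higher in ANT (0.503% against 0.352%), and a difference between the clones are likewise open.

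ANT replicates 1 and 3 stood apart from ANT replicates 4 and 5, along an axis that also set SAS replicate 1 (23.55) apart from SAS replicate 2 (−24.98), so the split is not a feature of ANT alone; the tests below cover ANT only. A GC content and length trend is argued against as the whole cause, since the mean correlation of deviations within the pairs was 0.327 before and 0.273 after its removal. The GC trend did run with the split. The rank correlation of deviations with GC content was −0.314 and −0.199 in ANT replicates 1 and 3, and 0.298 and 0.219 in ANT replicates 4 and 5. It was −0.31 in SAS replicate 1 and 0.257 in SAS replicate 2. SAS cells in an ANT library are argued against, since the Trav9-4 share was at most 1.10% in ANT and at least 35.5% in SAS. Immediate early and heat shock genes were higher in replicates 4 and 5, with a median log2 ratio of 0.49 at percentile 99.95 of 10000 lists matched on expression. The matched lists were drawn gene by gene and not matched on GC content. Members of the handling list move together (estimated correlation 0.305), and the split was itself found in these data. The percentile therefore cannot tell cell handling from such joint movement or from the GC trend, and handling stays open. No biological explanation was tested, as the labels set no group apart within either clone.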
